A study of Mus musculus with 12 samples.

How the data were processed

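Gene expression was measured in 12 mouse pancreas tumours, each on 1 one-colour expression array, with 3 tumours in each of 4 groups. Per the series text each group came from 3 mice, so every array is a separate animal. The groups were the FAP-TK control, FAP depleted, aSMA-TK control and aSMA depleted tumours, taken from the genotype in the labels. FAP is fibroblast activation protein and aSMA is alpha smooth muscle actin, encoded by Fap and Acta2. TK stands for thymidine kinase, which makes the cells that carry it sensitive to ganciclovir. Per the labels' protocols, ganciclovir was given at 50 ug per kg to deplete the FAP-positive or aSMA-positive cells, RNA was extracted with Trizol, and biotin-labelled cRNA was prepared with a kit for Illumina arrays. The labels give this dose for all 12 tumours and mark the controls only as having no depletion. Whether the controls in fact received ganciclovir is therefore not clear. If they did not, an effect of the treatment itself cannot be told apart from one of cell loss. The probe set identifiers are those of an Affymetrix whole-transcript array, so the label protocol and the value table name different array makers.

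The deposited file holds the authors' processed values for 72688 probe sets on each array. The scale was read from the values: the deposited values run from 1.64 to 19.93 with no negative value, as log2 intensities would, over a range of 18.29. That range is wider than a 16-bit scanner can record, so differences are given in these log2 units and are not converted to folds. Background correction, summarization and normalization are not given in the sources used here. The submitters' processing notes name limma, without a version. The column medians were higher on the arrays of the FAP line than on those of the aSMA line, so the deposited values were not equal in distribution between arrays.

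After 6732 control probe sets were left out, the 65956 other probe sets were quantile normalized between arrays. Values that were already normalized would have been kept as deposited, and the differing quantiles led to this step, before any comparison was computed. A probe set was given a gene where the platform annotation listed exactly 1 symbol. That held for 30604 of the 32750 listed probe sets, 2146 had several symbols, and 33206 probe sets had no listed gene. Symbols were updated through the gene identifier in the RefSeq gene table of assembly GRCm38.p6, which changed 827 of them. For the 355 genes with more than 1 probe set, the one with the highest mean over the 12 arrays was kept, which left 30142 genes. Dim genes were not removed.

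Linear models with 1 mean per group were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, so that all groups shared 1 estimate of spread. Moderated two-sided tests (empirical Bayes, no trend, not robust) were adjusted by the Benjamini-Hochberg method over the 30142 genes, and a gene was called at an adjusted p under 0.05. The comparisons were FAP depleted minus FAP-TK control, aSMA depleted minus aSMA-TK control, the difference between these effects, and aSMA-TK control minus FAP-TK control. Of 38 gene lists, 36 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists of the depletion targets and of erythroid and blood genes had too few measured members. In all, 481 of 525 list entries were measured. A list's members are shared in part with other lists, so the list results are not independent of each other. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives.

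Genes were named by a rule set before the data were examined. It takes Fap and Acta2. It then takes, per direction, the 10 genes of largest difference among those called. Where fewer were called, it fills up to 5 with the genes of smallest unadjusted p whose depleted and control values did not overlap, clone names left out. For each list called it takes the 4 members of smallest unadjusted p in the list's direction. For the myofibroblast, inflammatory fibroblast, T cell, regulatory T cell and IL-6 lists it takes 2 members even where the list was not called. Single measures were also compared by exact permutation tests, two-sided, for which 3 arrays against 3 cannot give a p under 0.1. The number of arrays limits the precision of every value.

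The model, the lists, the naming rule and most alternatives were set before the data were examined. The alternatives set then were median centring, a filter on dim genes, an offset of 50, averaging or testing all probe sets, only the groups compared, trended and robust variances, array weights, an adjusted p under 0.1, an unmoderated two-sample test, and leaving out each array in turn. The alternatives chosen after seeing the data were the values as deposited, the control-probe separation of each array as a covariate, the sex of the animal as a covariate, and the 3 arrays of low separation left out. Control-probe separation is the median of the 1324 positive-control probe sets minus that of the 5222 negative-control probe sets. Sex was read from Xist and Y-linked genes.

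The steps were tested on simulated data for the 30142 genes, with the spread of the real arrays and 50 genes changed at each size. Genes were drawn independently of each other, unlike real ones. All sizes were changed in the same simulated data, together with a shift of the whole acinar list. Many large changes loosen the Benjamini-Hochberg cutoff. The shares recovered at small sizes may thus be too high for the real data. For the FAP comparison 46% of genes changed by 1 log2 unit, 74% of those changed by 2, 98% by 4 and 100% by 8 were recovered, with 12 unchanged genes called. For the aSMA comparison the shares were 50%, 76%, 98% and 100%, with 19 unchanged genes called.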

Results

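Expression was measured in pancreas tumours of PKT mice, a genetic model of pancreatic ductal adenocarcinoma, in which FAP-positive or aSMA-positive cells had been depleted or left in place. Both cell populations belong to the stroma, the supporting tissue of fibroblasts, vessels and matrix around the tumour cells. The 12 tumours form 4 groups of 3, a depleted and a control group in each of 2 lines, and 30142 genes were tested. The arrays of the aSMA line had lower background than those of the FAP line. Their negative-control probe sets had a median deposited log2 value of 4.58 ± 0.14 (SD, n = 3) in the aSMA-TK controls and 4.65 ± 0.20 in the group labelled aSMA depleted, against 6.17 ± 0.48 in the FAP-TK controls and 5.83 ± 0.50 in the FAP depleted group. Control-probe separation was 2.97 and 2.99 in FAP-TK control replicates 1 and 3 and 2.69 in FAP depleted replicate 2, and it lay between 4.32 and 4.89 on the other 9 arrays. Pairs of arrays of the same group had a median correlation across genes of 0.979, pairs of the same line but other groups 0.979, and pairs from different lines 0.969.

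**Figure D1:**
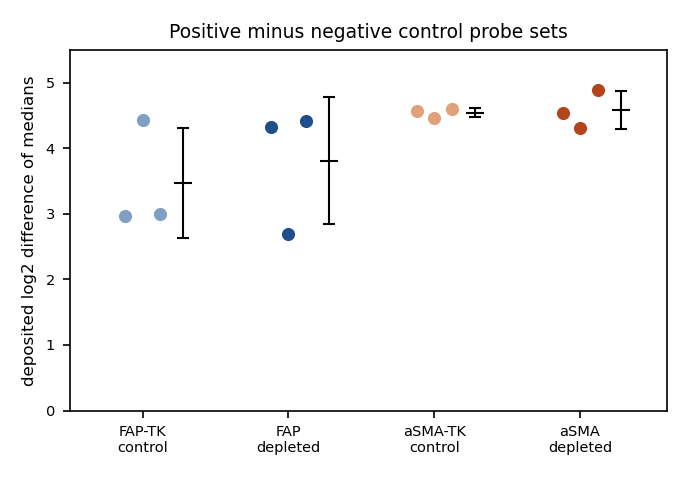
Control-probe separation of each array (deposited log2, points), with the mean and SD of each group of 3 beside the points. The lowest 3 arrays, at 2.69, 2.97 and 2.99, all belong to the FAP line.

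Fap, the gene that marks the cells depleted in the FAP line, had log2 values of 6.56, 7.31 and 6.53 in the FAP-TK control tumours and 5.52, 5.34 and 6.21 in the FAP depleted tumours. The depleted tumours were all below the controls, by -1.11 ± 0.37 (SE, n = 3 per group), with an exact permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 1.00. Acta2, which encodes alpha smooth muscle actin, had values of 12.26, 10.85 and 11.12 in the aSMA-TK control tumours and 10.13, 13.86 and 15.28 in the tumours labelled aSMA depleted. Its difference of 1.68 ± 1.71 (adjusted p = 0.949, exact permutation p = 0.4) does not show the loss that the label names. The spread is too wide to exclude that loss. The tumour at 10.13 lay below all controls, and Acta2 ran from 8.86 to 14.60 within the FAP-TK controls. These animals are therefore called the tumours labelled aSMA depleted. In the line that was not targeted, Acta2 differed by -1.69 ± 1.71 in the FAP depleted tumours and Fap by 0.34 ± 0.37 in the tumours labelled aSMA depleted. The Acta2 difference in the aSMA line ranged from 0.60 to 3.17 with 1 array left out. The Fap difference in that line turned to -0.05 without aSMA depleted replicate 3.

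**Figure D2:**
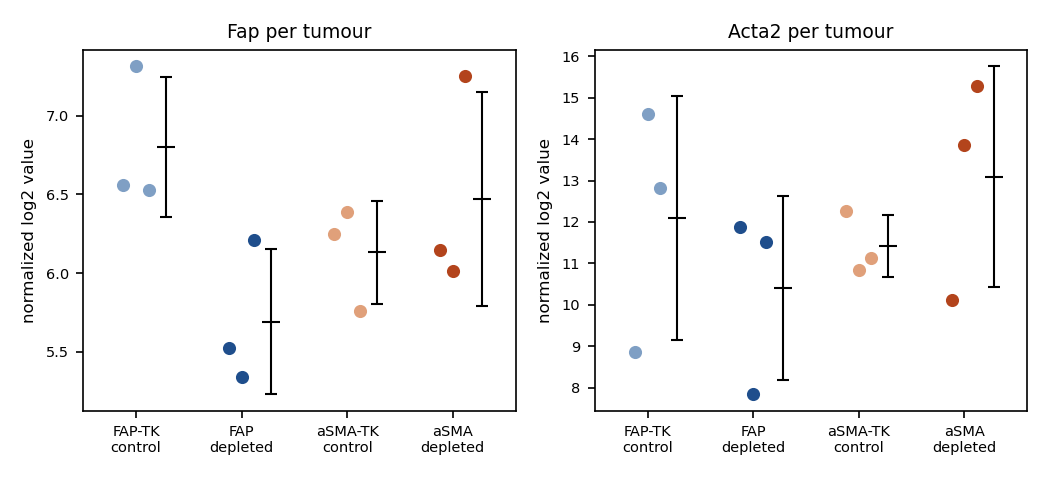
Normalized log2 values of Fap and Acta2 in each tumour (points), with the mean and SD of each group of 3. Fap was between 5.34 and 6.21 in the FAP depleted tumours and between 6.53 and 7.31 in their controls, while Acta2 in the tumours labelled aSMA depleted spanned 10.13 to 15.28.

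The comparison within the FAP line asked how the tumour changes when FAP-positive cells, mostly fibroblasts, are removed. As a list, p53 targets and DNA damage genes rose in the FAP depleted tumours, with 17 of 18 members higher and a median difference of 0.50 (adjusted p = 5.53e-05, and 0.874 as the adjusted p with an estimated correlation). Hedgehog signalling genes, which report the paracrine signal that tumour cells send to stroma, fell as a list by a median of -0.20 (adjusted p = 0.00462, and adjusted p = 0.874 with an estimated correlation). Acinar genes, which encode digestive enzymes, rose with 21 of 23 members higher and a median of 1.20 (adjusted p = 0.0134, and adjusted p = 0.874 with an estimated correlation). Fibroblast and matrix genes fell as lists, but not without FAP depleted replicate 2 alone. No single gene passed the test over all genes. For the means of the called lists, exact permutation p ran from 0.2 (p53 and acinar genes) to 0.9 (matrix genes). It was 0.4 for hedgehog and 0.7 for pan-fibroblast genes, so the list means of depleted and control tumours overlapped. Depleted and control values also overlapped for each of the 18 p53 and 13 pan-fibroblast members, while 8.10% of all genes did not overlap.

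Among the p53 targets, Zmat3 was higher by 0.50 ± 0.17 (SE, n = 3), Btg2 by 0.82 ± 0.29, Polk by 0.71 ± 0.29 and Pmaip1, which encodes the pro-apoptotic protein NOXA, by 1.65 ± 0.70. The list mean was 8.32 ± 0.27 (SD) in the controls and 8.86 ± 0.38 in the depleted tumours, and the list passed with each of the 12 arrays left out in turn. The p53 list also rose in the tumours labelled aSMA depleted, and camera did not call it in the difference between the effects (adjusted p = 0.327). Of the 8 hedgehog genes 5 were lower. The transcription factor Gli1, a direct target of the pathway, was at -0.85 ± 0.18 and passed when adjusted over the list alone (adjusted p = 0.00655). The receptor Ptch1 was at -1.10 ± 0.38, Gli2 at -0.44 ± 0.20 and Gli3 at -0.33 ± 0.19. The hedgehog mean of -0.27 went to -0.13 without FAP depleted replicate 2 (adjusted p = 0.0805) and to -0.09 without FAP-TK control replicate 2 (adjusted p = 0.0665), which ended the call.

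The pan-fibroblast list fell, with 12 of 13 members lower and a median of -0.57 (adjusted p = 0.0173, and adjusted p = 0.874 with an estimated correlation). Thy1 was at -0.93 ± 0.78, the proteoglycan gene Dcn at -1.36 ± 1.15 and the collagen gene Col1a2 at -0.92 ± 0.87. The myofibroblastic list also had 12 of 16 members lower with a median of -0.54 (adjusted p = 0.0173, and adjusted p = 0.874 with an estimated correlation), among them Cdh11 at -1.61 ± 0.56 and Tagln at -1.36 ± 1.27. Interstitial matrix genes had 16 of 24 members lower and a median of -0.32, and epithelial-mesenchymal transition genes 6 of 10 lower and a median of -0.15 (both adjusted p = 0.0376, and adjusted p = 0.874 with an estimated correlation). Bgn stood at -1.36 ± 1.12 (0.04 without FAP depleted replicate 2), Zeb1 at -0.61 ± 0.26 and Vim at -1.33 ± 0.85. The pan-fibroblast mean was 10.26, 7.71 and 10.39 in the depleted tumours and 9.05, 10.68 and 10.19 in the controls. FAP depleted replicate 2, the tumour at 7.71, was also an array of low control-probe separation. With that tumour left out the mean differences turned to 0.35 for pan-fibroblast (adjusted p = 0.827), 0.15 for myofibroblastic (adjusted p = 0.699), 0.50 for matrix (adjusted p = 0.477) and 0.15 for epithelial-mesenchymal transition genes (adjusted p = 0.939). With all arrays these means were -0.52, -0.52, -0.31 and -0.30. The same 4 calls ended without FAP-TK control replicate 2, where the means went toward 0 (-0.17, -0.00364, -0.05 and -0.02, adjusted p = 0.318, 0.469, 0.318 and 0.469). Without FAP-TK control replicate 3 they ended too (adjusted p = 0.146, 0.107, 0.318 and 0.123), although the means, at -0.41, -0.45, -0.18 and -0.31, moved little except that of matrix genes.

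Inflammatory fibroblast genes did not pass (12 of 17 lower, median -0.11, adjusted p = 0.151), with Svep1 at -1.03 ± 0.46 and the interleukin-1 receptor gene Il1r1 at -1.13 ± 0.56. T cell genes (8 of 13 lower, median -0.01, adjusted p = 0.300), regulatory T cell genes (5 of 8 lower, median -0.03, adjusted p = 0.244) and IL-6, JAK and STAT3 signalling genes (10 of 17 higher, median 0.10, adjusted p = 0.990) did not pass either. Only 1 of the 13 T cell and 1 of the 8 regulatory T cell genes were above background on most arrays. The tests of the T cell and regulatory T cell lists therefore cannot decide whether these cells changed. Cd4 was at -0.42 ± 0.50, Tnfrsf4 at -0.37 ± 0.17 and the cytokine gene Lif at 0.72 ± 0.26. Interferon response genes fell as a list, with 14 of 20 members lower but a median of only -0.10 (adjusted p = 0.0357, and adjusted p = 0.874 with an estimated correlation). The sensor gene Oas2 was at -0.65 ± 0.56 and Ifit1 at -0.41 ± 0.31. The interferon mean was -0.08, turned to 0.14 without FAP-TK control replicate 2 (adjusted p = 0.643) and to 0.04 without FAP depleted replicate 2 (0.144), and was -0.16 without FAP-TK control replicate 1 (0.0751), each ending the call. Proliferation genes fell with 14 of 19 members lower and a median of -0.15 (adjusted p = 0.0447, and adjusted p = 0.874 with an estimated correlation). The proliferation marker Mki67 was at -0.71 ± 0.58 and reversed to 0.50 without the 3 arrays of low separation. That call ended without FAP depleted replicate 2, where the mean turned from -0.12 to 0.16 (adjusted p = 0.941), without FAP-TK control replicate 2 (mean -0.02, 0.327) or 3 (mean -0.08, 0.318), and, with the mean kept at -0.12, without aSMA-TK control replicate 1 (0.0520).

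Of the acinar genes, the elastase gene Cela3b differed by 2.01 ± 0.92, Zg16 by 2.15 ± 1.01 and Pnliprp2 by 1.81 ± 1.02. Pnliprp2 was at 0.96 without FAP-TK control replicate 3, at 2.85 without FAP-TK control replicate 2, and reversed to -0.23 without the 3 arrays of low separation. Per tumour the acinar mean was 9.54, 7.91 and 8.90 after depletion and 6.77, 7.11 and 8.32 in the controls. The acinar call ended without 4 of the arrays while the mean difference, 1.38 with all of them, stayed high. It was 1.24 without FAP-TK control replicate 2 (adjusted p = 0.531), 1.07 without FAP-TK control replicate 1 (0.0751), 1.00 without FAP depleted replicate 1 (0.0625) and 1.82 without FAP depleted replicate 2 (0.0782). Ductal epithelial genes rose as a list, with 14 of 17 higher and a median of 0.52 (adjusted p = 0.0317, and adjusted p = 0.874 with an estimated correlation). The tight junction gene Cldn7 was at 0.86 ± 0.24, the keratin genes Krt7 at 0.90 ± 0.28 and Krt8 at 1.33 ± 0.62, and Cldn4 at 1.94 ± 0.87. This call ended as the mean went from 0.36 to 0.15 without FAP-TK control replicate 1 (0.144), 0.20 without FAP-TK control replicate 3 (0.302), 0.18 without FAP depleted replicate 1 (0.0812) and 0.15 without FAP depleted replicate 3 (0.153).

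Immediate early genes, which respond to stress and tissue handling, rose with 9 of 9 members higher and a median of 0.68 (adjusted p = 0.0420, and adjusted p = 0.874 with an estimated correlation). Fos was at 1.93 ± 1.32 and Atf3 at 0.68 ± 0.46. The list mean was 9.83 in FAP depleted replicate 3, against 7.09 and 6.41 in the other depleted tumours, and without that tumour the mean difference turned from 0.82 to -0.21 (adjusted p = 0.487). The call also ended without FAP-TK control replicate 1 (mean 0.50, 0.315), FAP-TK control replicate 2 (mean 0.97, 0.226) or aSMA-TK control replicate 1 (mean 0.82, 0.0508). Hypoxia and glycolysis genes (12 of 15 higher, median 0.38) and TGF-beta signalling genes (12 of 15 higher, median 0.30) rose as lists, both with adjusted p = 0.0447, and adjusted p = 0.874 with an estimated correlation. The glycolytic enzyme gene Pgk1 was at 1.32 ± 0.45, Ndrg1 at 1.36 ± 0.55, Ltbp1 at 1.33 ± 0.40 and Smad3, a transcriptional mediator of TGF-beta, at 1.07 ± 0.27. Smad3 passed when adjusted over the list alone (adjusted p = 0.0455). The hypoxia mean of 0.50 went to 0.03 without FAP depleted replicate 3 (0.770) and to 0.28 without FAP-TK control replicate 1 (0.552). Its call ended with a higher mean without FAP depleted replicate 2 (0.73, adjusted p = 0.0964) or FAP-TK control replicate 2 (0.63, adjusted p = 0.226), and with the mean still 0.50 without aSMA depleted replicate 1 (0.0696) or aSMA-TK control replicate 1 (0.0525) or 2 (0.0568). The TGF-beta mean of 0.29 went to -0.12 without FAP-TK control replicate 1 (adjusted p = 0.733), to -0.00219 without FAP depleted replicate 1 (0.450) and to 0.00312 without FAP depleted replicate 3 (0.364). It stayed at 0.28 without aSMA depleted replicate 3 (0.0531) and at 0.29 without aSMA depleted replicate 1 (0.0539) or aSMA-TK control replicate 1 (0.0525) or 2 (0.0568), where the call ended as well.

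Other settings that kept all arrays, or left out the 3 of low separation, also moved these calls. The p53 list passed in 11 of 11, with adjusted p from 2.54e-05 to 0.0241. With array weights the calls ended for acinar (adjusted p = 0.319), hedgehog (0.308), pan-fibroblast (0.430), myofibroblastic (0.361), interferon (0.571), hypoxia (0.975) and, all at 0.485, matrix, epithelial-mesenchymal transition, proliferation and immediate early genes. The means were then 0.02 for pan-fibroblast, 0.07 for hedgehog, 0.17 for interferon, -0.10 for myofibroblastic, 0.11 for matrix, 0.07 for epithelial-mesenchymal transition and 0.07 for proliferation genes, while those of acinar (1.35), immediate early (0.61) and hypoxia genes (0.29) stayed above 0. Leaving out the arrays of low separation sets 2 depleted arrays against 1 control array, with a spread that comes mostly from the aSMA line, so calls lost there say little. They were those for pan-fibroblast (0.360), matrix (0.606), ductal (0.222), proliferation (0.652), TGF-beta (0.412), hypoxia (0.231) and, at 0.0586, immediate early and epithelial-mesenchymal transition genes. Fitted on the FAP line alone, calls ended also for matrix (0.0625), ductal and epithelial-mesenchymal transition (both 0.0743), immediate early (0.0991), TGF-beta (0.0996) and hypoxia genes (0.110), and an offset of 50 ended that for proliferation genes (0.0753). Over all these settings the adjusted p ran from 4.93e-07 to 0.319 for acinar, from 0.000122 to 0.308 for hedgehog, from 1.07e-05 to 0.430 for pan-fibroblast, from 1.07e-05 to 0.361 for myofibroblastic, from 1.07e-05 to 0.606 for matrix, from 0.000322 to 0.485 for epithelial-mesenchymal transition, from 0.000959 to 0.222 for ductal, from 0.0101 to 0.571 for interferon and from 0.00515 to 0.652 for proliferation genes. It ran from 0.0351 to 0.485 for immediate early, from 0.0439 to 0.975 for hypoxia and from 0.00389 to 0.795 for TGF-beta genes, which passed in 6, 5 and 4 of 11 settings. With separation as a covariate the TGF-beta mean was -0.02.

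In the FAP comparison limma called 0 of 30142 genes, the smallest adjusted p was 0.785, and 1117 genes (3.71%) had an unadjusted p under 0.05, 799 higher and 318 lower. An unmoderated two-sample test also called 0 genes. The groups did not overlap for 2440 genes (8.10%), where chance gives 10%. The genes of smallest p on the higher side were Prap1 at 5.10 ± 0.78, Crybg1 at 1.91 ± 0.31, Dennd11 at 1.14 ± 0.19, Snord69 at 1.28 ± 0.21 and Card14 at 0.57 ± 0.10. Prap1, which encodes a secreted proline-rich acidic protein, averaged 10.62 ± 1.47 (SD) in the controls and 15.72 ± 0.75 after depletion. On the lower side were Pbld2 at -0.41 ± 0.07, the Rab GTPase-activating protein gene Tbc1d4 at -1.03 ± 0.19, Lacc1 at -1.17 ± 0.23, Mir674 at -0.66 ± 0.13 and Tcirg1, a subunit of the vacuolar proton pump, at -1.42 ± 0.29. Without FAP depleted replicate 2 limma called 4 genes, chosen here after their values were seen. They were Plat, which encodes tissue plasminogen activator, at 3.77 ± 0.37, the integrin gene Itgb4 at 1.94 ± 0.19, Dennd11 at 1.39 ± 0.13 and the amino acid transporter gene Slc7a1 at 1.37 ± 0.14. The other 23 lists did not pass (adjusted p from 0.0566 to 0.990), and camera called 13 of the 36 lists, or 0 with an estimated correlation and 0 by fry.

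**Figure D3:**
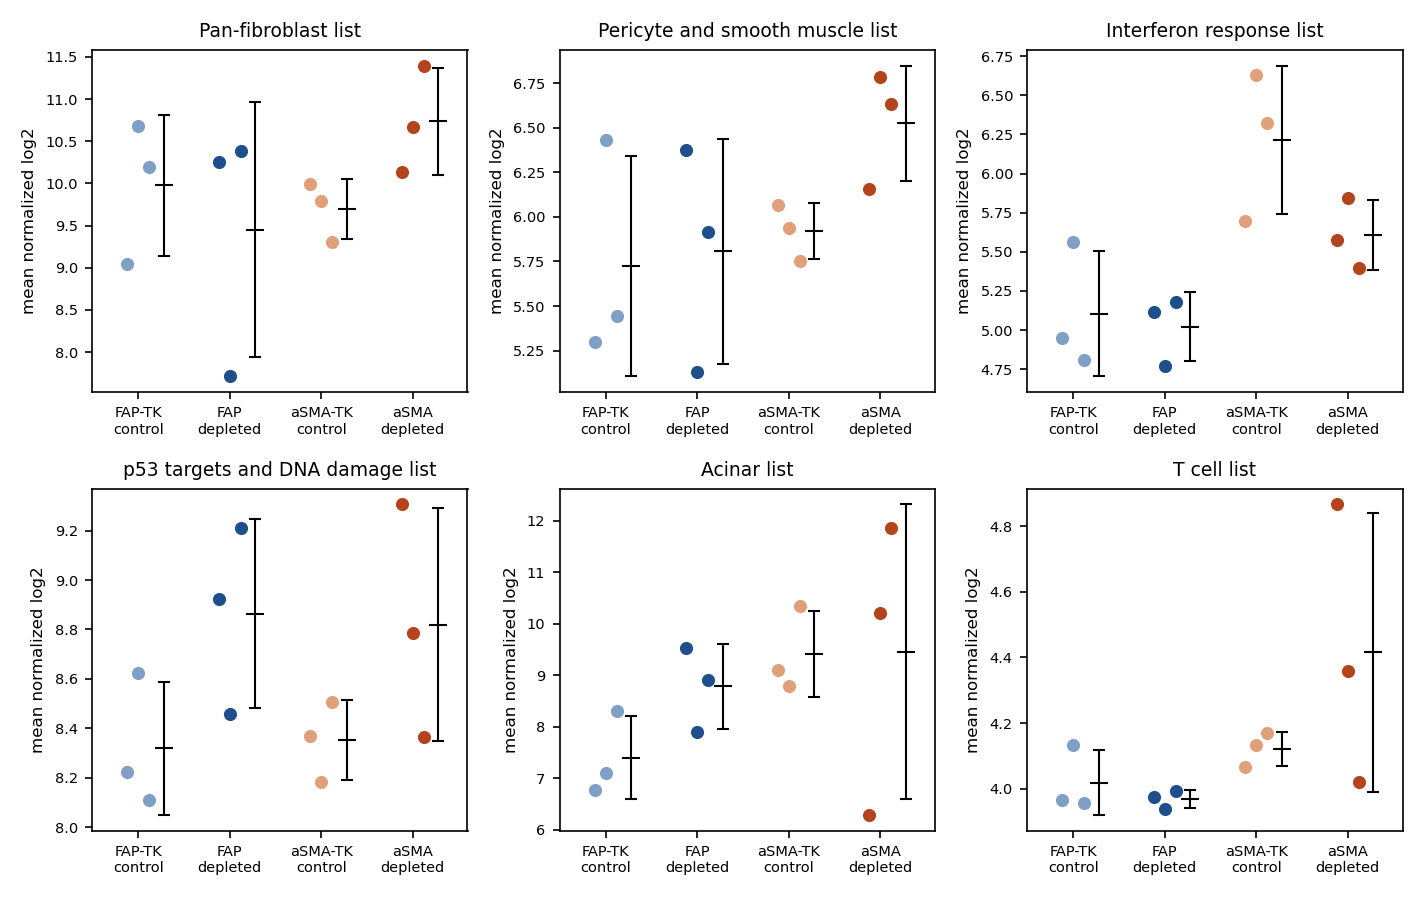
Mean normalized log2 value of the measured members of 6 gene lists in each tumour (points), with the mean and SD of each group of 3. The pan-fibroblast mean of one FAP depleted tumour, at 7.71, and the T cell mean of one tumour labelled aSMA depleted, at 4.87, stand apart from the other members of their groups.

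The comparison within the aSMA line asked the same of aSMA-positive cells, which include myofibroblasts and the smooth muscle and pericytes of vessels. In the tumours labelled aSMA depleted, interferon response genes fell as a list, with 18 of 20 members lower and a median of -0.67 (adjusted p = 3.91e-07, and adjusted p = 0.771 with an estimated correlation). Pericyte and smooth muscle genes rose, with 14 of 14 members higher and a median of 0.56 (adjusted p = 0.000318, and adjusted p = 0.771 with an estimated correlation). Pan-fibroblast genes rose with 13 of 13 members higher and a median of 1.06, and regulatory T cell genes with 7 of 8 higher and a median of 0.27 (both adjusted p = 0.00217, and adjusted p = 0.771 with an estimated correlation). Only 1 of the 8 regulatory T cell and 10 of the 20 interferon genes were above the antigenomic 95th percentile on most arrays. No single gene passed over all genes. For the means of the called lists, exact permutation p ran from 0.1 (pericyte and pan-fibroblast genes among others) to 0.4 (T cell and proliferation genes). It was 0.2 for interferon and 0.3 for regulatory T cell genes. Since Acta2 did not show the loss that the label names, these directions belong to the tumours labelled depleted.

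Interferon-induced Ifit1 was at -1.17 ± 0.31 (SE, n = 3), Oas2 at -1.58 ± 0.56, Oas1a at -1.17 ± 0.43 and the signal transducer gene Stat2 at -0.77 ± 0.31. The list mean was 6.21 ± 0.48 (SD) in the aSMA-TK controls and 5.61 ± 0.22 in the tumours labelled depleted, and 5.11 ± 0.40 in the FAP-TK controls. The pericyte channel genes Abcc9 and Kcnj8 were at 1.32 ± 0.45 and 1.15 ± 0.43, and Mylk, the smooth muscle myosin kinase gene, at 0.46 ± 0.24. Epithelial-mesenchymal transition genes rose with 10 of 10 members higher and a median of 0.38 (adjusted p = 0.00496, and adjusted p = 0.771 with an estimated correlation). Cdh2, which encodes N-cadherin, was at 1.31 ± 0.34 and passed when adjusted over the list alone (adjusted p = 0.0366). The interferon, pericyte, regulatory T cell and epithelial-mesenchymal transition calls held with each of the 12 arrays left out in turn.

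Among fibroblast genes, Dcn stood at 2.71 ± 1.15, Mmp2 at 1.56 ± 0.99 and Pdpn, which encodes podoplanin, at 1.21 ± 0.68. The pan-fibroblast mean was 10.14, 10.67 and 11.40 in the tumours labelled depleted and 9.99, 9.80 and 9.30 in the controls, and its call ended without aSMA depleted replicate 3 (adjusted p = 0.119) or aSMA-TK control replicate 3 (0.0542), with mean differences of 0.71 and 0.84 against 1.04. Acinar genes did not pass (14 of 23 higher, median 0.29, adjusted p = 0.538), but their mean was 6.29, 10.21 and 11.86 in these tumours, 9.45 ± 2.86 (SD) against 9.41 ± 0.83 in the controls. The acinar difference was -1.16 without aSMA depleted replicate 3 and 1.63 without replicate 1. Inflammatory fibroblast genes rose with 13 of 17 members higher and a median of 0.47 (adjusted p = 0.00521, and adjusted p = 0.771 with an estimated correlation). The chemokine gene Cxcl12 was at 0.98 ± 0.26, Il1r1 at 1.48 ± 0.56 and Gpx3 at 2.08 ± 0.84. That call ended without aSMA depleted replicate 2 (mean 0.22 against 0.59, adjusted p = 0.405). Myofibroblastic genes (15 of 16 higher, median 0.61) and interstitial matrix genes (19 of 24 higher, median 0.45) were just short of the threshold, both with adjusted p = 0.0507, as were ductal epithelial genes (12 of 17 lower, median -0.39) at the same adjusted p. The collagen gene Col12a1 was at 2.07 ± 0.98 and Mmp11 at 0.57 ± 0.34.

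IL-6, JAK and STAT3 signalling genes rose with 15 of 17 members higher and a median of 0.45 (adjusted p = 0.00400, and adjusted p = 0.771 with an estimated correlation). The receptor genes Osmr, Il6ra and Il6st were at 1.27 ± 0.41, 1.13 ± 0.42 and 1.12 ± 0.51, and Lbp at 1.93 ± 0.78. Without aSMA depleted replicate 2 the mean went from 0.61 to 0.34 and the adjusted p was 0.0908. Macrophage genes rose with 16 of 17 members higher and a median of 0.58 (adjusted p = 0.0340, and adjusted p = 0.771 with an estimated correlation). The mannose receptor gene Mrc1 was at 2.54 ± 1.43 and the complement gene C1qb at 1.97 ± 1.29. This call ended without aSMA-TK control replicate 1 (0.0548) or 2 (0.152), and without aSMA depleted replicate 2 (0.138), with means of 0.86, 0.56 and 0.70 against 0.83. Hypoxia and glycolysis genes (11 of 15 higher, median 0.51, adjusted p = 0.0297) and p53 targets (14 of 18 higher, median 0.19, adjusted p = 0.0294) also rose as lists, both with adjusted p = 0.771 with an estimated correlation. Adm was at 1.73 ± 0.97, Vegfa at 0.75 ± 0.47, Mdm2 at 0.77 ± 0.39 and the cell cycle inhibitor gene Cdkn1a at 1.20 ± 0.68. The hypoxia call ended without aSMA depleted replicate 2 (0.505) or aSMA-TK control replicate 1 (0.0657) or 2 (0.134), with means of 0.24, 0.44 and 0.37 against 0.51. The p53 call ended without aSMA depleted replicate 1 (0.401) or 2 (0.0692) or aSMA-TK control replicate 2 (0.102), with means of 0.22, 0.48 and 0.38 against 0.47.

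T cell genes (12 of 13 higher, median 0.17) and B and plasma cell genes (11 of 11 higher, median 0.19) rose as lists, both with adjusted p = 0.00400, and adjusted p = 0.771 with an estimated correlation. Only 1 of 13 T cell, 1 of 11 B and plasma cell and 1 of 8 liver genes were above the antigenomic 95th percentile on most arrays, so these lists rest on signals near background. Cd3e, a chain of the T cell receptor complex, was at 0.99 ± 0.33, Cd4 at 0.93 ± 0.50, Jchain, the joining chain of secreted antibodies, at 1.78 ± 0.78, and the B cell gene Ms4a1 at 0.72 ± 0.41. Of the regulatory T cell genes, Icos was at 0.51 ± 0.17, Ctla4 at 0.43 ± 0.15 and Il2ra at 0.36 ± 0.13. Liver genes rose with 8 of 8 members higher and a median of 0.33 (adjusted p = 0.00490, and adjusted p = 0.771 with an estimated correlation), among them Ttr at 0.85 ± 0.52. Proliferation genes fell with 18 of 19 members lower and a median of -0.28 (adjusted p = 0.00400, and adjusted p = 0.771 with an estimated correlation). The replication helicase gene Mcm6 was at -0.62 ± 0.29 and Top2a at -0.72 ± 0.53. The calls for T cell, B cell, liver and proliferation genes all ended without aSMA depleted replicate 1 (adjusted p = 0.785, 0.816, 0.823 and 0.785), where the means went from 0.29, 0.36, 0.40 and -0.30 to 0.07, 0.07, 0.10 and -0.03. That for proliferation genes also ended without aSMA-TK control replicate 2 (mean -0.06, 0.422).

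Over the other settings with all arrays, or without the 3 of low separation, adjusted p ran from 5.96e-08 to 6.33e-05 for interferon, from 3.52e-06 to 0.00287 for pericyte, from 5.61e-07 to 0.0253 for pan-fibroblast and from 3.64e-05 to 0.00994 for IL-6 genes, which passed in all 11. Epithelial-mesenchymal transition (8.92e-05 to 0.0216), regulatory T cell (0.000861 to 0.00800) and T cell genes (0.000287 to 0.0339) also passed, the first in 11 of 11 settings and the others in the 10 that could be run, since without dim genes the T cell, regulatory T cell, B and plasma cell and liver lists had fewer than 5 members. With array weights the calls ended for B and plasma cell and proliferation genes (both adjusted p = 0.0528), p53 targets (0.0553) and liver genes (0.0844). Sex as a covariate ended those for inflammatory fibroblast (0.0648) and macrophage genes (0.213), and leaving out the arrays of low separation that for hypoxia genes (0.0534). These 7 values are each list's largest, and the smallest were 0.000213 for B cell, 0.000358 for proliferation, 0.000446 for p53, 0.000593 for liver, 0.000215 for inflammatory fibroblast, 8.91e-05 for macrophage and 0.000943 for hypoxia genes.

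In the aSMA comparison limma called 0 of 30142 genes, the smallest adjusted p was 0.474, and 1450 genes (4.81%) had an unadjusted p under 0.05, 744 higher and 706 lower. The unmoderated two-sample test called 0 genes as well. The groups did not overlap for 3773 genes (12.5%), where chance gives 10%. The gene of smallest p was Wnt4, a secreted Wnt ligand, at 1.85 ± 0.23, which averaged 5.75 ± 0.26 (SD) in the controls and 7.59 ± 0.46 in the tumours labelled depleted. Next on the higher side were Hspb7 at 2.25 ± 0.47, Sod3, the extracellular superoxide dismutase gene, at 0.66 ± 0.14, Rpl30-ps11 at 0.72 ± 0.15 and Trav10n at 0.63 ± 0.14. On the lower side were Aadac at -1.49 ± 0.27, the water channel gene Aqp5 at -0.69 ± 0.13, Tas2r121 at -0.78 ± 0.12, Smcp at -0.55 ± 0.09 and Vmn2r-ps7 at -0.53 ± 0.08. Without aSMA depleted replicate 3 limma called 16 genes, of which 12 were immunoglobulin variable segments. The count was 1 without aSMA-TK control replicate 1, the class II gene H2-Ea at -4.48 ± 0.19, chosen here after its value was seen. H2-Ea was at 3.58 to 3.98 in the tumours labelled depleted, where the antigenomic 95th percentile averaged 4.91 (deposited log2). The size of its difference is therefore uncertain. The control left out was itself at 3.96, while aSMA-TK control replicates 2 and 3 were at 7.96 and 8.59. The call thus rests on those animals and on leaving out the control that did not share their high values. The other 22 lists did not pass (adjusted p from 0.0507 to 0.996), and camera called 14 of 36 lists, or 0 with an estimated correlation and 0 by fry.

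The difference between the groups labelled depleted and control in the aSMA line, minus that in the FAP line, was tested, with the reservation that Acta2 was not lower in the tumours labelled aSMA depleted. Pan-fibroblast genes moved apart most clearly, with 13 of 13 members higher in this difference and a median of 1.43 (adjusted p = 0.000616, and adjusted p = 0.869 with an estimated correlation). Epithelial-mesenchymal transition genes (10 of 10 higher, median 0.71, adjusted p = 0.00277) and regulatory T cell genes (6 of 8 higher, median 0.36, adjusted p = 0.00572) also differed, with adjusted p = 0.869 with an estimated correlation. Dcn differed by 4.07 ± 1.62 (SE), Fstl1 by 2.45 ± 1.37, Vim by 2.76 ± 1.20, Zeb1 by 1.03 ± 0.36, Cdh11 by 2.26 ± 0.80 and Icos by 0.62 ± 0.24. Hedgehog genes differed by a median of 0.64 with 6 of 8 higher (adjusted p = 0.00736, and adjusted p = 0.869 with an estimated correlation), and 2 members passed when adjusted over the list alone (smallest adjusted p = 0.0361). Gli1 was at 0.88 ± 0.25 and Ptch1 at 1.75 ± 0.54. These 4 calls held with each array left out in turn, but sizes depended on single arrays. Without FAP depleted replicate 2 the mean FAP effect went from -0.52 to 0.35 for pan-fibroblast genes. For epithelial-mesenchymal transition genes it went from -0.30 to 0.15, so both differences were smaller. The hedgehog FAP effect went from -0.27 to -0.09 without FAP-TK control replicate 2.

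Ductal epithelial genes differed the other way, with 15 of 17 members lower and a median of -1.20 (adjusted p = 0.00736, and adjusted p = 0.869 with an estimated correlation). Krt7 was at -1.34 ± 0.40 and Cldn7 at -1.20 ± 0.34. The call ended without aSMA-TK control replicate 3 (mean -0.62 against -0.80, adjusted p = 0.0636). Interferon genes were lower in 18 of 20 members with a median of -0.47 (adjusted p = 0.0329, and adjusted p = 0.869 with an estimated correlation), with Gbp2 at -1.75 ± 1.07. That call, with a mean of -0.52, ended without 6 of the arrays. The mean was -0.47 without aSMA-TK control replicate 3 (adjusted p = 0.0636), -0.65 without FAP depleted replicate 2 (0.0762), -0.45 without FAP-TK control replicate 1 (0.0836), -0.42 without aSMA depleted replicate 3 (0.0977), -0.38 without FAP-TK control replicate 3 (0.197) and -0.32 without aSMA-TK control replicate 2 (0.524).

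Myofibroblastic (median 1.17, adjusted p = 0.00676), interstitial matrix (0.94, adjusted p = 0.00736), pericyte and smooth muscle (0.45, adjusted p = 0.00736), inflammatory fibroblast (0.92, adjusted p = 0.00748) and macrophage genes (1.10, adjusted p = 0.00748) were higher in the difference, each with adjusted p = 0.869 with an estimated correlation. Col12a1 was at 2.66 ± 1.38, Il1r1 at 2.61 ± 0.80, Cxcl12 at 1.36 ± 0.37, Mylk at 0.88 ± 0.34 and Marco at 2.13 ± 1.33. Without FAP depleted replicate 2 all 5 of these calls ended (adjusted p = 0.0762, 0.338, 0.117, 0.0762 and 0.226), as the means went from 1.23, 0.97, 0.52, 0.69 and 1.17 to 0.57, 0.16, 0.18, 0.38 and 0.29. Others ended without FAP-TK control replicate 2 (myofibroblastic 0.0797, pericyte 0.161, macrophage 0.167, means 0.72, 0.17 and 0.57), FAP-TK control replicate 3 (matrix 0.0541, inflammatory fibroblast 0.0920, macrophage 0.164, means 0.84, 0.54 and 0.76), aSMA depleted replicate 3 (myofibroblastic 0.0977, matrix 0.260, means 0.75 and 0.58), aSMA depleted replicate 2 (inflammatory fibroblast 0.134, mean 0.32) or aSMA-TK control replicate 3 (matrix 0.0789, pericyte 0.0636, means 0.82 and 0.44). T cell genes (12 of 13 higher, median 0.17, adjusted p = 0.00736) and B and plasma cell genes (10 of 11 higher, median 0.13, adjusted p = 0.0254) differed as lists, both with adjusted p = 0.869 with an estimated correlation. Cd3e was at 1.08 ± 0.46 and Mzb1, a plasma cell gene, at 0.31 ± 0.22. Both of these calls ended without aSMA depleted replicate 1 (adjusted p = 0.305 and 0.803), as the means went from 0.34 and 0.32 to 0.12 and 0.02. That for B cells also ended without aSMA-TK control replicate 1 (0.0646) or 3 (0.0636) or FAP-TK control replicate 1 (0.101), with means of 0.29, 0.32 and 0.32.

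Over the other settings with all arrays, or without the 3 of low separation, adjusted p ran from 8.74e-08 to 0.00437 for pan-fibroblast, from 1.01e-05 to 0.0246 for epithelial-mesenchymal transition, from 1.01e-05 to 0.0233 for myofibroblastic, from 6.27e-06 to 0.0355 for macrophage and from 0.000222 to 0.0381 for ductal genes, which passed throughout. It ran from 0.000906 to 0.0818 for hedgehog and from 0.000180 to 0.268 for pericyte genes, the larger values with array weights, where the hedgehog mean was -0.05. For regulatory T cell (0.00392 to 0.0742), inflammatory fibroblast (0.00188 to 0.187), T cell (0.00437 to 0.140) and interferon genes (0.0143 to 0.599) the larger values came with the 3 arrays of low separation left out, which leaves 1 FAP-TK control array. Matrix genes (1.01e-05 to 0.0639) had their largest with sex as a covariate and ended also without the low arrays (0.0639). The T cell, regulatory T cell and B and plasma cell lists, near background, could not be run without dim genes. B and plasma cell genes (0.00437 to 0.226) passed in 4 of 9 settings and interferon genes in 5 of 10. T cell and interferon genes also ended in the values as deposited (both 0.0641) and centred on the array medians (0.0523 and 0.0541), and interferon genes with separation (0.0714) or sex (0.107) as a covariate.

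In the difference limma called 0 genes (smallest adjusted p = 0.829), and 1796 (5.96%) had an unadjusted p under 0.05, 630 higher and 1166 lower. The genes of smallest p were Lacc1 at 1.80 ± 0.32, Slc43a3 at 4.76 ± 0.91, Trav10n at 1.00 ± 0.19, Pbld2 at 0.53 ± 0.10 and Zfp534 at 0.83 ± 0.17 on the higher side. On the lower side they were Ccer1 at -0.97 ± 0.15, Ccdc25 at -1.72 ± 0.29, Vmn2r-ps7 at -0.56 ± 0.11, Prps1l1 at -0.79 ± 0.16 and Sel1l3 at -1.58 ± 0.31. Slc43a3, a purine base transporter gene, averaged 10.94 in the FAP-TK controls, 8.94 in the FAP depleted tumours, 8.67 in the aSMA-TK controls and 11.43 in the tumours labelled aSMA depleted. Fap itself differed by 1.45 ± 0.53 and Acta2 by 3.37 ± 2.42. H2-Ea was the 1 gene called without aSMA-TK control replicate 1 (-4.33 ± 0.26), chosen here after its value was seen. It was near background in the other groups, so this size is uncertain. The control left out was near background too, at 3.96, so the call rests on aSMA-TK control replicates 2 and 3. The other 23 lists did not pass (adjusted p from 0.0521 to 0.854), IL-6, JAK and STAT3 signalling genes being nearest with a median of 0.40 and Osmr at 1.48 ± 0.57. Camera called 13 of 36 lists, or 0 with an estimated correlation and 0 by fry. Across genes the FAP and aSMA effects had a Pearson correlation of -0.288 and a Spearman correlation of -0.220, with genes not being independent replicates. Of 113 genes with an unadjusted p under 0.05 in both comparisons, 34 had the same sign, where independent lists would share 53.7 genes in all. Both comparisons use the same estimate of spread for each gene, so their p-values are not independent. The excess over 53.7 can therefore not be read as a shared response. The correlation was -0.0602 without FAP depleted replicate 2 and -0.423 without FAP depleted replicate 3.

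The control tumours of the 2 lines were compared with each other, where line and array background go together and cannot be told apart. Interferon response genes were higher in the aSMA-TK controls in 20 of 20 members, with a median of 1.13 (adjusted p = 6.46e-05, and adjusted p = 0.989 with an estimated correlation). Proliferation genes were higher in 19 of 19 members with a median of 0.90 (adjusted p = 0.00149), and islet genes, which encode hormones and their processing enzymes, in 13 of 13 with a median of 0.67 (adjusted p = 0.0258), both with adjusted p = 0.989 with an estimated correlation. Examples from these lists, chosen after their values were seen, are Ifit1 at 1.90 ± 0.31 (SE, n = 3, adjusted p = 0.0123), Gbp3 at 1.27 ± 0.28 (adjusted p = 0.0311), Mcm6 at 1.86 ± 0.29 (adjusted p = 0.0116) and Pcsk1 at 0.67 ± 0.09 (adjusted p = 0.00644). Pcsk1 averaged 3.57 in the FAP-TK and 4.25 in the aSMA-TK controls, where the antigenomic 95th percentile averaged 5.66 and 4.83 (deposited log2). Ifit1 (4.63) and Gbp3 (4.85) were near background in the FAP-TK controls, so the sizes for these genes and Pcsk1 are uncertain. Only 7 of 13 islet and 10 of 20 interferon genes were above that percentile on most arrays. Of the interferon genes 4 passed over all genes and 13 when adjusted over the list alone. In the values as deposited the median gene differed by -0.39 and the interferon mean by 0.42, the islet mean by 0.29 and the proliferation mean by 0.04, with 15 of 20, 10 of 13 and 10 of 19 members above 0, and camera, which compares a list with the other genes, still called all 3. Over the 4 other scalings and fits tried, adjusted p ran from 1.10e-06 to 0.0141 for interferon, from 0.00135 to 0.201 for proliferation and from 7.06e-05 to 0.136 for islet genes. With separation as a covariate the mean differences went from 0.91 to 0.38 for islet genes (9 of 13 higher), from 0.88 to 0.45 for proliferation genes (17 of 19) and from 1.11 to 0.82 for interferon genes (20 of 20). Without the arrays of low separation, on 1 FAP-TK control array, they were 0.26 (9 of 13), 0.67 (18 of 19) and 0.65 (17 of 20). Proliferation genes did not pass when arrays were centred on their medians (0.201), nor islet genes then (0.112) or without the arrays of low separation (0.136). The islet call ended without aSMA-TK control replicate 3 (mean 0.51, adjusted p = 0.242) or FAP depleted replicate 2 (mean 0.90, 0.0553).

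Between these control groups limma called 2350 genes, 1440 higher and 910 lower in the aSMA-TK controls, with a smallest adjusted p of 0.000899. An unadjusted p under 0.05 was found for 8488 genes (28.2%), and 10564 genes (35.0%) did not overlap, where chance gives 10%. Among called genes of largest difference, chosen after their values were seen, the mucosal genes Olfm4 and Tff3 were higher by 3.10 ± 0.76 and 2.53 ± 0.56, and the nuclear RNA gene Neat1 was at -4.04 ± 0.70. Olfm4 and Tff3 averaged 4.99 and 4.40 in the FAP-TK controls, where the antigenomic 95th percentile averaged 5.66 (deposited log2). Their differences are thus against signals near background, and the sizes are uncertain. The count was 12443 in the values as deposited, with 424 higher and 12019 lower, so the balance of higher and lower calls depends on the scaling. Whether genes called under both scalings changed direction was not tested. It was 383 with the 3 arrays of low separation left out (85 higher, 298 lower), where 1 FAP-TK control array remained, 1012 with separation as a covariate (452 higher, 560 lower), and between 506 without aSMA-TK control replicate 2 and 3115 without FAP-TK control replicate 2. It also moved by over 1.5 times without FAP-TK control replicate 1 (844) or 3 (599), FAP depleted replicate 1 (1394), or aSMA-TK control replicate 1 (659) or 3 (1281).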

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

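The tests on array background, on Acta2 against the stromal lists and on the fibroblast genes were chosen only after the results were seen, as were the values as deposited, the separation and sex covariates and the fits without the 3 arrays of low separation. The gene lists below stood out because the effects in the 2 lines differed. Values are medians of the aSMA effect minus the FAP effect, and with an estimated correlation the adjusted p of each is 0.869. Pan-fibroblast genes differed by 1.43 in 13 of 13 members (adjusted p = 0.000616). The size of this difference rests in part on 1 tumour, since the mean FAP effect went from -0.52 to 0.35 without FAP depleted replicate 2. Epithelial-mesenchymal transition genes differed by 0.71 in 10 of 10 (adjusted p = 0.00277) and regulatory T cell genes by 0.36 with 6 of 8 higher (adjusted p = 0.00572). Myofibroblastic genes differed by 1.17 with 15 of 16 higher (adjusted p = 0.00676). At an adjusted p of 0.00736 were interstitial matrix genes (0.94, 20 of 24 higher), hedgehog genes (0.64, 6 of 8 higher), pericyte and smooth muscle genes (0.45, 12 of 14 higher), ductal epithelial genes (-1.20, 15 of 17 lower) and T cell genes (0.17, 12 of 13 higher). At 0.00748 were inflammatory fibroblast genes (0.92, 12 of 17 higher) and macrophage genes (1.10, 15 of 17 higher). B and plasma cell genes differed by 0.13 with 10 of 11 higher (adjusted p = 0.0254), and interferon genes by -0.47 with 18 of 20 lower (adjusted p = 0.0329).

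Other splits of the same arrays put these counts in proportion. For the difference 100 splits were drawn, and 32 gave as many called lists as the real 13 (highest other 21), so chance is not excluded. For the correlation of the effects, each line has 10 splits, and 10 of the 100 combinations were as large as the real -0.288 (highest other 0.471 in size), so chance is not excluded there either. The comparisons of 3 against 3 have only 10 splits, too few for a share under 0.05. In the FAP comparison 2 of 10 splits gave as many lists as the real 13 (highest other 14), and in the aSMA comparison 3 of 10 as many as the real 14 (highest other 15). Where limma called 0 genes in the real split, a count of splits as large holds all of them by construction (10 of 10, 10 of 10 and 100 of 100) and says nothing about chance. The highest others were 2883 in the FAP comparison (real 0, 1117 at an unadjusted p under 0.05), 193 in the aSMA comparison (real 0, 1450) and 1004 in the difference (real 0, 1796), and the unmoderated test also called 0 in the FAP and aSMA comparisons. Between the control groups 1 of 10 splits gave the real 2350, with 0 in the highest other.

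The split of the FAP line that called 2883 genes set FAP-TK control replicates 1 and 3 and FAP depleted replicate 2 against the other 3 arrays, which points to a structure of the arrays. These are the 3 arrays of low control-probe separation, at 2.97, 2.99 and 2.69. That structure crosses the FAP groups and called more genes than the real split. With these arrays left out limma called 13 genes in the FAP comparison, 2 higher and 11 lower, on 1 control array and 2 depleted arrays.

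The control tumours of the 2 lines differed by 2350 genes. A difference in array background may be the source. The negative-control median of the aSMA-TK controls differed from that of the FAP-TK controls by -1.59 ± 0.29 (SE) in deposited log2, and the array medians over genes by -0.42. These medians do not link background to the genes called, so they cannot decide whether it is the source. With control-probe separation as a covariate the median size of the called genes' differences went from 0.72 to 0.66, a ratio of 0.911. That ratio ignores direction, and the share of calls that were higher went from 61.3% to 44.7%. Separation had an SD of 0.84 in the FAP-TK controls and only 0.07 in the aSMA-TK controls. The covariate fit therefore cannot decide whether separation is the source. With that covariate 1012 genes were called, 671 of them among the 2350, as the median standard error rose from 0.145 to 0.164 while the differences shrank. Biological differences between the lines stay open and untested, since the labels give no processing date and line and array background go together.

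Acta2 was not lower in the tumours labelled aSMA depleted, at 1.68 ± 1.71 (SE, exact permutation p = 0.4). More stroma overall in these tumours may be the source, and Acta2 minus the pan-fibroblast mean was 0.64 ± 1.25, which leaves a loss of Acta2 per fibroblast and its absence open. More smooth muscle or pericytes could also be the source, and Acta2 minus the pericyte and smooth muscle mean was 1.07 ± 1.43. The spread of Acta2 within the groups keeps both open. Incomplete depletion and a wrong label were not tested.

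Fibroblast genes were lower in the FAP depleted tumours, by a pan-fibroblast mean of -0.52, and a single tumour may be the source, since without FAP depleted replicate 2 the mean was 0.35. With the 3 arrays of low separation left out, that tumour among them, it was -0.37 on 1 control array (adjusted p = 0.360, with a range over settings from 1.07e-05 to 0.430), which leaves this open. With control-probe separation as a covariate the mean was -0.93 ± 0.44 (SE). FAP depleted replicate 2 was the lowest of all arrays both in separation (2.69) and in pan-fibroblast mean. The covariate fit therefore cannot decide whether separation is the source. Dilution by epithelial or acinar cells could lower all stromal genes alike, but the endothelial and the pericyte and smooth muscle means were not lower, at 0.04 and 0.08. The endothelial shift minus the pan-fibroblast shift was 0.56 ± 0.65, and this spread leaves dilution and a loss of fibroblasts open. Removal of FAP-positive cells, which the labels name, stays among the open explanations.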

How the results depend on the processing

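The tests with values as deposited, with separation or sex as a covariate and with 3 arrays of low separation left out were chosen after the data were seen. The rest were set before the data were examined. Fap and Acta2 kept their direction in their own lines, and neither passed, under each setting tried. Of 200 results for named genes, in 4502 fits, 4493 kept direction and side of the threshold, 7 reversed and 2 became called. Since the main fits called 0 genes and the named genes were picked from these same arrays, this count was largely set beforehand. It is no measure of stability.

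No gene was called by limma in the FAP, aSMA or difference comparison under any setting that left out no array of the groups compared (1117, 1450 and 1796 at an unadjusted p under 0.05), and the unmoderated test called 0 in the FAP and aSMA comparisons. In the FAP comparison 13 were called with 3 arrays of low separation left out, which leaves 1 FAP-TK control array. Leaving out single arrays gave from 0 to 4 genes (4 without FAP depleted replicate 2, among them Dennd11 at an adjusted p of 0.0349). In the aSMA comparison it gave from 0 to 16 (16 without aSMA depleted replicate 3, with Wnt4 at 0.0462), and in the difference from 0 to 1 (1 without aSMA-TK control replicate 1).

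The control comparison gave 2350 genes and 5769 with centred arrays, 589 without dim genes, 1536 with an offset of 50, 8599 for every probe set, 212 with only the 2 groups, 6658 with array weights, 5104 at an adjusted p under 0.1, 12443 as deposited, 1012 with separation as a covariate and 383 without the arrays of low separation. It gave 506 without aSMA-TK control replicate 2 and 3115 without FAP-TK control replicate 2. The share higher was 61.3%, against 3.41% as deposited, 46.5% for every probe set, 44.7% with the covariate and 22.2% without the low arrays. Fewer arrays in the fit account in part for 212 and 383, and the cause of the other moves was not tested.

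Of the lists, 13 were called in the FAP comparison, 8 with only the 2 groups, 5 with array weights, 8 without the low arrays, and from 3 (without FAP-TK control replicate 2) to 15 (without aSMA depleted replicate 2) with single arrays left out. The aSMA comparison gave 14, and from 14 to 20 over all settings at the preset correlation. The difference gave 13, and from 7 (without FAP depleted replicate 2) to 16 (without aSMA depleted replicate 3). With an estimated correlation, and by fry, 0 lists were called in each of the FAP, aSMA and difference comparisons, where camera's preset gave 13, 14 and 13. The list calls thus depend on the assumed correlation between genes.

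The correlation of effects was -0.288, and -0.0504 with array weights, -0.0973 without the low arrays, and from -0.423 (without FAP depleted replicate 3) to -0.0602 (without FAP depleted replicate 2). Among named genes, Col6a1 reversed to 0.0620 (FAP) and Tnfrsf17 to -0.00838 (difference) with array weights, Pnliprp2 to -0.23 and Mki67 to 0.50 (both FAP) without the low arrays. With single arrays left out Bgn ran from -2.38 to 0.0430 and Snai2 from -0.76 to 0.0515 (FAP), reversing without FAP depleted replicate 2 and FAP-TK control replicate 2, and Fap in the aSMA line from -0.0520 (without aSMA depleted replicate 3) to 0.57. The cause was not tested.

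Quantile normalization as an alternative was not run, since it is the method used. No paired analysis was possible because the labels number the mice individually and share no number between groups. Control-probe separation was lowest on 3 arrays of the FAP line, and how far this limits dim genes was not tested. The antigenomic 95th percentile (deposited log2) was 5.48, 5.82 and 5.31 on these arrays. On the other arrays of that line it was 5.69, 5.68 and 5.01.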

Other observations

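The tests that count immunoglobulin segments and read sex were chosen after the values were seen, as were H2-Ea, Pgc and Plat, while Jchain, Prap1, Wnt4 and the lists were set or named by rules fixed earlier. H2-Ea, a class II gene that some inbred strains do not express, was at 7.96 and 8.59 in aSMA-TK control replicates 2 and 3 and between 3.45 and 3.98 on the other 10 arrays. The gastric protease gene Pgc was at 11.05, 13.17 and 6.53 in the tumours labelled aSMA depleted and at 5.19 ± 0.75 (SD, n = 3) in their controls. Jchain was at 8.50, 5.88 and 4.64 in the tumours labelled aSMA depleted. The mean of 199 immunoglobulin variable segments was 6.47, 5.47 and 4.37 there and 4.44 ± 0.14 in their controls, with 190 of 199 higher in the group mean of the tumours labelled depleted. In the FAP depleted tumours 138 of 199 were higher, and their mean was 4.22 ± 0.24 against 4.09 ± 0.03 in the controls. The antigenomic 95th percentile averaged 5.33 and 5.66 in these groups (deposited log2), so this count rests on signals near background.

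Plat, which was called without FAP depleted replicate 2, was at 12.94, 9.59 and 12.83 in the FAP depleted tumours and at 8.41, 9.81 and 9.11 in their controls. Prap1 was at 15.19, 15.38 and 16.57 in the FAP depleted tumours, and at 14.59, 14.86 and 15.13 in the tumours labelled aSMA depleted against 11.30, 12.50 and 13.85 in the aSMA-TK controls. Wnt4 was at 8.12, 7.41 and 7.25 in the tumours labelled aSMA depleted and between 5.29 and 6.07 on the other 9 arrays.

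By Xist and Y-linked genes, FAP-TK control replicate 3, FAP depleted replicate 1, aSMA-TK control replicate 1 and aSMA depleted replicates 2 and 3 came from females and the other 7 from males. The first principal component held 36.8% of the variance and the second 17.0%. The erythroid and blood list, with 3 measured members, had a mean of 5.19 ± 0.25 (SD) in the FAP-TK controls and 4.71 ± 0.16 after depletion (exact permutation p = 0.1), and differed by 0.16 in the aSMA line (exact permutation p = 0.8). The list of the depletion targets, Fap and Acta2, differed by -1.40 in the FAP line and 1.01 in the aSMA line (exact permutation p = 0.4 in each).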
